A study of Homo sapiens with 24 samples.

How the data were processed

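RNA was isolated from HCT116 tumor xenografts, per the labels' protocols, and libraries were made with a stranded mRNA kit. The labels place 30 mice in 6 groups of 5, female and male R2G2 mice given phosphate buffered saline or 1 or 10 mg/kg asparagine, and 24 libraries, 4 per group, were analysed here. All libraries carry the same batch label. Each library stands for the tumor of a separate mouse in the labels, so the spread between libraries includes that between animals.

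The deposited values are a signal that the authors made by normalizing gene counts, in a table per sex with 12 libraries each, and are called normalized counts here. Software listed per the submitters' processing notes was CASAVA 1.8.2, Trim Galore 0.5.0 and HISAT2 2.1.0 with the hg38 genome, without further roles. The counting tool, its strand setting, the normalizing tool, the annotation release and any step that set mouse reads apart from human reads are not given in the sources used here. Reads of mouse cells in the tumor that align to human genes would add to the values, most where sequences are conserved. Both tables list protein-coding genes only, so levels of other RNA classes were not analysed here. Within each library 100% of the values were whole multiples of 1 step (within 0.01), so whole reads were recovered by dividing by that step. The totals ranged from 26048864 to 78841354 reads in females and from 56115043 to 80682431 in males. The steps matched DESeq2 median-of-ratios factors, computed from the recovered reads of each table, within 0.000244% and 0.000459%. Such factors set the median gene equal between libraries, so a change of most genes in 1 direction would not be seen. The tables were scaled separately, and their values are not on 1 scale. The 10 most abundant genes took 7.14% to 14.7% of the values in females and 5.15% to 11.0% in males, and mitochondrially encoded transcripts 5.45% to 15.1% and 1.55% to 10.9%. Gene identifiers were matched to an hg38 annotation (19804 found) and to current symbols (19726 found), and 27 symbols that had been turned into dates in the tables were restored from their identifiers. No column was left unused.

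Before the data were examined, the groups, tests, alternatives, 39 gene lists and the rule for named genes were fixed. Genes with a mean of at least 10 normalized counts in a table were tested on log2(value + 1) with limma (version 3.58.1 in R 4.3.3) and a trend in the prior variance. The 3 groups of a sex shared 1 fit, with two-sided p and Benjamini-Hochberg adjustment at 0.05. Fold changes are on the log2(value + 1) scale, which understates the change of genes with low values. Sex differences were tested in a fit of all 24 libraries as the female effect minus the male effect, over genes that passed the filter in both tables, and only effects within a table entered that difference. Lists with at least 3 measured members were tested with camera at its preset correlation of 0.01, adjusted over the lists of a comparison. They were tested again with a correlation estimated per list and with fry, a self-contained test of whether members move, on balance, in 1 direction. No list passed with an estimated correlation or by fry in any of the 8 contrasts. Members were also adjusted over the list alone. The lists, which hold 1083 members of which 1078 are in the tables, cover asparagine, aspartate and glutamine metabolism, amino acid transporters, ATF4 targets, aminoacyl-tRNA synthetases, mTORC1 signalling, estrogen synthesis, and estrogen receptors and induced genes. They also cover cell cycle phases, hypoxia, glycolysis, lipid and nucleotide synthesis, interferon, antigen presentation, NF-kB, p53, apoptosis, protein folding, NRF2 and OXPHOS. The rest are mitochondrial transcripts, ribosomes and their biogenesis, histones, immediate early genes, WNT targets, differentiation, epithelial-mesenchymal transition, autophagy, enterocyte and goblet genes and markers of 7 other cell types. HCT116 itself expresses part of the marker lists, such as collagens and keratins. The core genes CYP19A1, ASNS, ESR1, ESR2 and GPER1 were tested with a two-sided exact permutation test of 4 against 4 libraries, which cannot give a p below 0.0286, adjusted over 20 tests. A single gene at that smallest p therefore could not pass after adjustment.

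Genes named were those past the threshold whose groups did not overlap, up to 10 per direction, and, where fewer than 5 qualified, also the 5 with the smallest p per direction. For the sex differences they were the 10 with the smallest p. Up to 4 members with the smallest p were named from each list that passed or had a member past the threshold, besides the core genes. Clone-based names, uncharacterized loci, small RNAs, antisense genes and symbols ending in P and digits were left out of naming. As a departure decided after values were seen, Y-linked genes and XIST were left out of naming too. Some named members of a list are not reported here.

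Alternatives were pseudocounts of 0.5 and 5, no filter and a mean of at least 50, rescaling to the same total, by the upper quartile and and by TMM. Others were a fit of only the compared groups, the replicate number as a block, a constant prior variance, array weights, edgeR (4.0.16) quasi-likelihood tests and DESeq2 (1.42.0) on recovered reads, and leaving out each library in turn. edgeR called 1, 1, 0, 0, 0, 0, 0 and 0 genes and DESeq2 6, 8, 3, 9, 15, 5, 14 and 46 in the order of the comparisons in the report. Chosen after seeing the data were a total without mitochondrial transcripts and leaving out the 2 male 10 mg/kg libraries with the lowest mitochondrial share. The fits were tested on simulated counts drawn from the real means and depths. Each gene was drawn on its own, so variation shared between genes was absent. The changed genes came from those with a mean of at least 50 in both tables. The rates may therefore differ in the real libraries and for genes of lower level. In the simulation limma recovered 74% of genes changed 2-fold and 92% of those changed 4-fold for 10 mg/kg against vehicle in females (13794 genes). It recovered 81% and 96% in males (13865 genes) and 47% and 94% for the sex difference at 10 mg/kg (13665 genes). Among simulated calls 4.05%, 2.75% and 4.73% were unchanged genes with limma and 15.2%, 13.2% and 13.7% with DESeq2. Replicates differed from one another by more than counting error in every pair. Tables and plots were made with Python 3.11.15, numpy 2.4.6, pandas 2.3.3 and matplotlib 3.10.9.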

Results

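Messenger RNA was sequenced from tumor xenografts of HCT116, a human colon cancer cell line, grown in female and male R2G2 mice, an immunodeficient strain. The mice received vehicle (phosphate buffered saline) or asparagine, the amino acid made by asparagine synthetase, at 1 or 10 mg/kg. The data held 24 libraries in 6 groups of 4, and n = 4 applies to every group mean below. Read totals recovered from the values ran from 26048864 to 78841354 in the female table and from 56115043 to 80682431 in the male table. Between 14132 and 15329 of the listed protein-coding genes had at least 1 read in a female library, and between 14806 and 15111 in a male library. The 2 tables were normalized separately. Levels were therefore compared only within a sex, and the sexes were compared only through their treatment effects.

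The series set out to compare how asparagine acts on tumors in females and males, with estrogen and aromatase in view. The genes of asparagine synthesis and estrogen signalling were examined first. ASNS, which encodes asparagine synthetase (ENSG00000070669.16, chromosome 7, 97852118 to 97872542 on hg38), was expressed at 2854 ± 377 normalized counts (SD, n = 4) in female vehicle tumors, 3088 ± 621 at 1 mg/kg and 3123 ± 570 at 10 mg/kg. In male tumors ASNS stood at 3716 ± 483, 3637 ± 145 and 3463 ± 406 in the same order. The log2 differences from vehicle were 0.10 and 0.12 in females and -0.02 and -0.10 in males (exact permutation p = 0.6, 0.514, 0.8 and 0.429, two-sided), all smaller than the spread between libraries. GPER1, the membrane estrogen receptor (ENSG00000164850.14, chromosome 7, 1082208 to 1093815), was the most abundant of the 3 estrogen receptor genes. Its level was 363 ± 41.1 in female vehicle tumors, 324 ± 7.25 at 1 mg/kg and 476 ± 79.2 at 10 mg/kg, against 338.5 ± 75.1, 488 ± 24.7 and 450 ± 78.4 in male tumors. GPER1 was higher in every male 1 mg/kg library than in any male vehicle library (log2 difference 0.55, exact permutation p = 0.0286, the smallest p that 4 against 4 libraries allow). After adjustment over the 20 tests of these genes the p was 0.381. A single gene could not pass this adjustment even at the smallest p, so the adjusted p cannot decide on any 1 gene. The differences at 10 mg/kg were 0.38 in females (exact p = 0.0571) and 0.42 in males (exact p = 0.114). CYP19A1, the aromatase gene (ENSG00000137869.14, chromosome 15, 51208057 to 51338610), had between 0 and 11 reads per library. Its group means were 5.50 ± 4.04, 2.94 ± 2.56 and 4.68 ± 3.55 normalized counts in females and 2.91 ± 3.36, 4.18 ± 5.41 and 4.59 ± 3.36 in males, from vehicle to 10 mg/kg. A difference in aromatase mRNA was not detectable at this depth (exact p from 0.543 to 0.771). ESR1, the nuclear receptor alpha (chromosome 6, 151656691 to 152129619), had reads in 3 of 24 libraries, with at most 6 reads in any of them. ESR2, the nuclear receptor beta (chromosome 14, 64084232 to 64338112), had 2 to 33 reads per library. Its mean was 15.3 ± 7.10 at 1 mg/kg in females against 6.10 ± 2.94 with vehicle (log2 difference 1.18, exact p = 0.0571, adjusted p = 0.381).

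**Figure D1:**
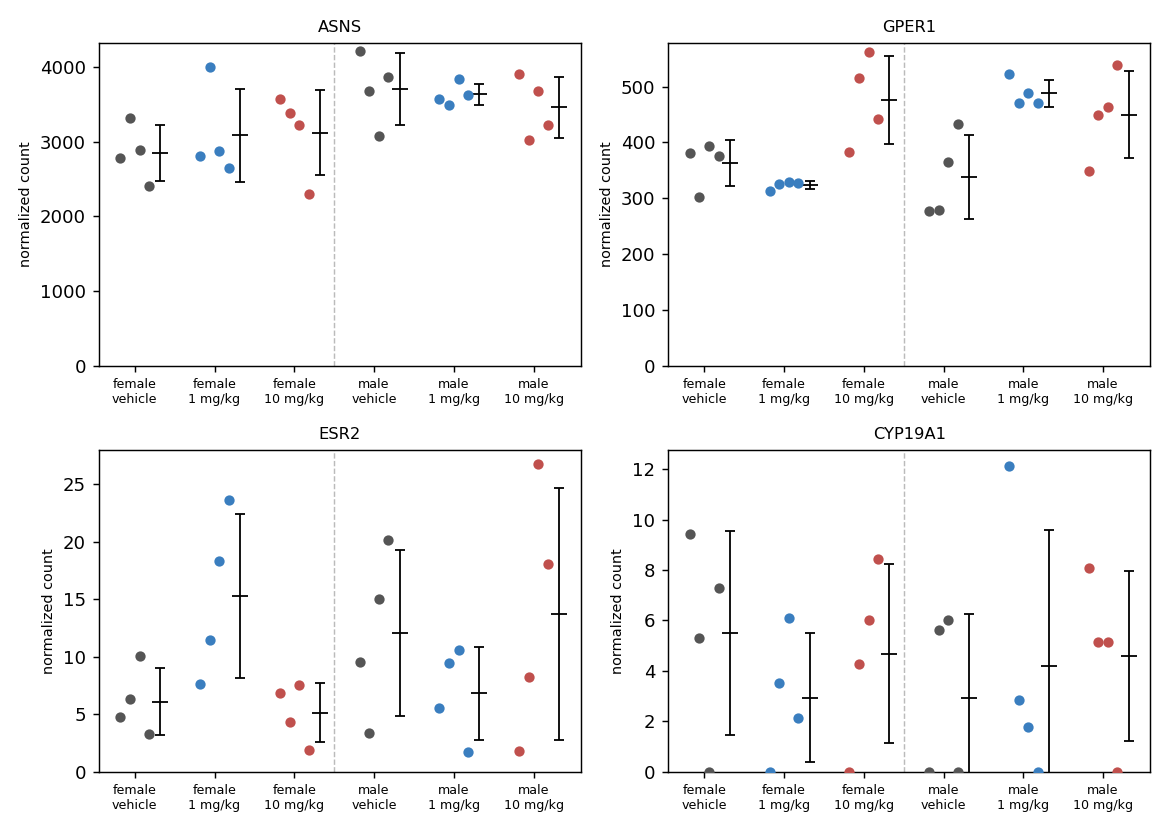
Normalized counts of ASNS, GPER1, ESR2 and CYP19A1 in each of the 24 libraries, by host sex and dose; points are single libraries and the black mark beside them is the group mean with its SD, drawn from an axis that starts at 0, so that bars reaching below 0 are clipped. Female and male values come from tables normalized separately; ASNS stands between 2854 and 3716 in the vehicle group means, while CYP19A1 stays at 5.50 or less in every group mean.

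In female mice the 1 mg/kg dose was set against vehicle to see how the tumor transcriptome differed at the lower dose. Genes controlled by NF-kB, the transcription factor of inflammatory signalling, lay higher as a group. Of the list 18 of 23 measured members had a positive log2 difference, with a median of 0.33. Among them BIRC3, an inhibitor of apoptosis, stood at 3984 ± 2032 against 1406 ± 222 normalized counts (log2 difference 1.35, SE 0.36). NFKBIA, the inhibitor that holds NF-kB in the cytoplasm, was at 4949 ± 1554 against 3140 ± 506 (0.62, SE 0.20). Hypoxia-induced genes were higher in 28 of 30 members (median 0.13), among them the carbonic anhydrase CA12 (0.37, SE 0.16) and the pyruvate dehydrogenase kinase PDK1 (0.30). Ribosomal protein genes were lower in 52 of 57 members (median -0.11) and interferon-stimulated genes in 34 of 42 (median -0.12), with IFI27 at -1.10 (SE 0.40). By camera with its preset correlation the adjusted p was 2.07e-08 for the NF-kB list, 3.83e-06 for hypoxia, 0.000199 for ribosomal proteins and 0.00305 for interferon-stimulated genes. For each of these lists adjusted p = 0.846 with an estimated correlation. The other called lists were glycolysis enzymes (median 0.10), ribosome biogenesis and MYC-induced genes (0.09), S phase genes (0.08), cytosolic heat shock genes (-0.09) and canonical histones (-0.34). That made 9 of 37 lists, the others also with adjusted p = 0.846 with an estimated correlation. No member of any list passed when adjusted over the list alone. A single gene passed the test over all 13827 genes: AC004922.1 (ENSG00000284292.1, chromosome 7, 99325879 to 99394653). This gene model runs through ARPC1A and ARPC1B and shares exons with both on the same strand, and its count is uncertain. AC004922.1 fell from 3469 ± 1143 to 333 ± 28.7 normalized counts (log2 difference -3.30, SE 0.34, limma adjusted p = 0.00228), with 1049 ± 577 at 10 mg/kg. Male means were 1867.5 ± 2615 with vehicle, 2294 ± 1409 at 1 mg/kg and 1442 ± 962 at 10 mg/kg. The gene is named after its values were seen, since its clone-based name lies outside the naming rule. Other genes with small p did not pass over all genes. ELK3, an ETS repressor, was 8113 ± 316 against 5624 ± 597 (0.53, SE 0.11). The signalling adaptor TRAF3 was at 0.53 (SE 0.13), the serpin SERPINA3 at 0.93 (SE 0.26), PALM3 at -0.62 (SE 0.16) and PARN at -2.29 (SE 0.40, adjusted p = 0.354). At an unadjusted p under 0.05 there were 192 genes, where chance gives 691, and 480 without vehicle replicate 4. The groups did not overlap for 167 genes (1.21%, where chance gives 2.86%). Leaving out 1 mg/kg replicate 1 left 4 called lists and leaving out replicate 4 left 16, while leaving out replicate 3 gave 2 called genes. Of the 9 lists the NF-kB list was the only 1 that passed without any single library: the interferon list turned direction without 1 mg/kg replicate 1 (adjusted p = 0.639) and the ribosomal proteins without vehicle replicate 2 (0.8286), and the hypoxia list did not pass without 1 mg/kg replicate 1 (0.121). S phase genes turned direction without 1 mg/kg replicate 2 (0.303) and histones without vehicle replicate 2 (0.854).

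At 10 mg/kg in female mice the same vehicle libraries were used, so calls made at both doses are not an independent repeat. The lists with the smallest camera p were ribosomal proteins, heat shock genes and immediate early genes. All 57 ribosomal protein genes measured were lower (median log2 difference -0.21), as were 17 of 19 cytosolic heat shock genes (median -0.28) and 23 of 24 immediate early genes (median -0.35). The co-chaperone BAG3 was at -0.40 (SE 0.10), the collagen chaperone SERPINH1 at -0.49 (SE 0.12), DNAJB1 at -0.92 (SE 0.26) and HSPH1 at -0.68 (SE 0.23). When adjusted over the list alone 6 heat shock genes passed, these among them with adjusted p of 0.0137, 0.0137, 0.0228 and 0.0491. Of the immediate early genes the transcription factor EGR3 was at -1.21 (SE 0.43) and JUN at -0.63, with none of the list past its own threshold. By camera the adjusted p was 4.31e-11 for ribosomal proteins, 2.66e-07 for heat shock genes and 3.54e-07 for immediate early genes. For each of them adjusted p = 0.994 with an estimated correlation. Canonical histones (median -0.51, with copies of near-identical sequence), unfolded protein response genes (-0.14), hypoxia-induced genes (-0.13) and nuclear-encoded OXPHOS subunits (-0.10) were lower. Aminoacyl-tRNA synthetases (0.12), cholesterol synthesis genes (0.17), S phase genes (0.10) and G2 and M phase genes (0.08) were higher. That made 11 of 37 lists, with adjusted p between 0.994 and 0.997 with an estimated correlation. SLC1A3, a transporter of glutamate and aspartate, was lower at 881 ± 289 against 2110 ± 383 normalized counts (log2 difference -1.30, SE 0.22, adjusted p = 0.331 over all genes). It was the only 1 of 28 amino acid transporters that passed when adjusted over the list alone (adjusted p = 0.00134). Of 22 measured estrogen receptor and estrogen-induced genes 3 passed when adjusted over the list alone. They were the receptor corepressor NRIP1 (0.88, SE 0.21, adjusted p = 0.0171), the ubiquitin ligase SIAH2 (-0.43, SE 0.11, adjusted p = 0.0206) and the retinoic acid receptor RARA (-0.51, SE 0.15, adjusted p = 0.0365). The list itself did not pass (camera adjusted p = 0.287). PARN, a ribonuclease that shortens poly(A) tails (ENSG00000140694.16, chromosome 16, 14435701 to 14632728), was the single gene that passed over all 13827 genes. It fell from 169 ± 46.6 normalized counts with vehicle to 17.0 ± 5.25 at 10 mg/kg (log2 difference -3.24, SE 0.40, limma adjusted p = 0.0163), with 36.4 ± 18.8 at 1 mg/kg. Genes below that threshold included ELK3 (0.52, SE 0.11), TRAF3 (0.50), the ephrin receptor EPHA7 (2.07, SE 0.51), the innate immune receptor TLR1 (1.11, SE 0.29) and PALM3 (-0.89, SE 0.16). At an unadjusted p under 0.05 there were 684 genes, where chance gives 691, with 1301 without vehicle replicate 4 and 436 without 10 mg/kg replicate 3. The groups did not overlap for 366 genes (2.65%, where chance gives 2.86%). Of the 11 lists 4 passed without any single library: the ribosomal proteins, heat shock genes, immediate early genes and unfolded protein response genes. OXPHOS subunits turned direction without vehicle replicate 2 (adjusted p = 0.856). The 4 higher lists did not pass without 10 mg/kg replicate 1, the library with the fewest reads, while the 7 lower lists did. Without it the adjusted p was 0.230 for aminoacyl-tRNA synthetases, 0.247 for cholesterol synthesis, 0.429 for S phase and 0.560 for G2 and M phase genes. PARN did not pass without vehicle replicate 1, 2 or 4 (adjusted p = 0.118, 0.140 and 0.114) or without 10 mg/kg replicate 1, 2 or 4 (0.0538, 0.0924 and 0.0787). Its log2 difference without single libraries lay between -3.43 and -3.08. The adjusted p of PARN over all alternatives ran from 7.61e-10 to 0.140.

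**Figure D2:**
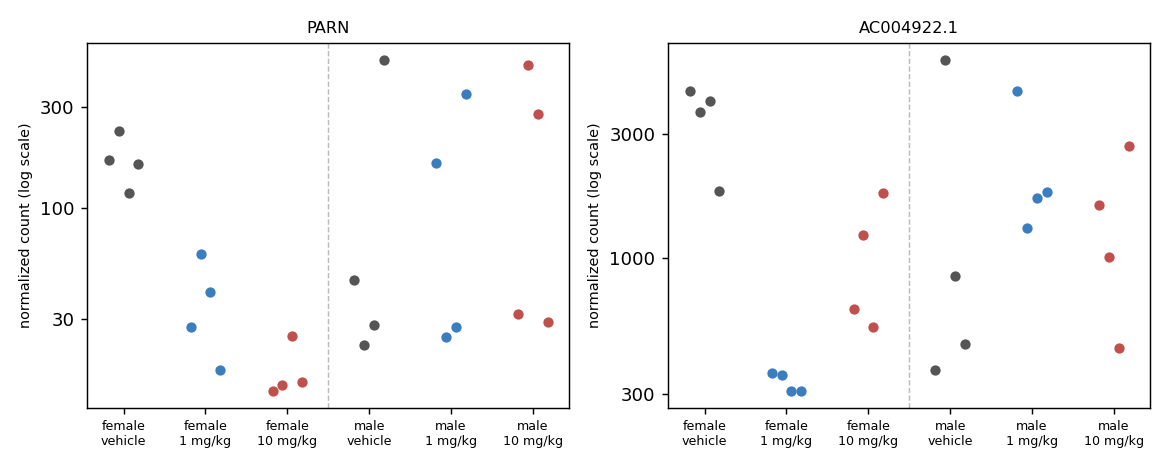
Normalized counts on a log axis of PARN and AC004922.1 in each of the 24 libraries, by host sex and dose; each point is a library, and female and male values come from tables normalized separately. PARN averaged 169 in female vehicle tumors and 17.0 at 10 mg/kg, while male group means of 149, 140 and 203 covered libraries far apart; AC004922.1 averaged 3469 in female vehicle tumors, 333 at 1 mg/kg and 1049 at 10 mg/kg, and 1867.5, 2294 and 1442 in males.

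The doses were also set against each other in female mice. This contrast reuses libraries already compared with vehicle and is not independent of those comparisons. Hypoxia-induced genes were lower at 10 than at 1 mg/kg in 30 of 30 members (median log2 difference -0.26), with the secreted glycoprotein STC2 at -0.57, the vasodilator peptide ADM at -0.54, the sterol regulator INSIG2 at -0.46 and ANKRD37 at -0.75. Immediate early genes were lower in 23 of 24 members (median -0.41), including the transcription factors MYC (-0.36, SE 0.12), JUNB (-0.42) and KLF4 (-0.39). NF-kB and cytokine genes were lower in 23 of 23 members (median -0.23) and interferon-stimulated genes higher in 41 of 42 (median 0.24). By camera the adjusted p was 2.04e-17, 1.98e-12, 5.79e-06 and 2.86e-08 in that order, against adjusted p = 0.371, 0.371, 0.496 and 0.589 with an estimated correlation. Of 37 lists 15 passed. Ribosomal proteins (median -0.12), heat shock genes (-0.18), ribosome biogenesis and MYC-induced genes (-0.08), OXPHOS subunits (-0.09), unfolded protein response genes (-0.08), glycolysis enzymes (-0.12), the estrogen receptor and estrogen-induced genes (-0.14, camera adjusted p = 0.0482), and apoptosis genes (-0.06) were lower. Cholesterol synthesis genes (0.12), aminoacyl-tRNA synthetases (0.08) and G2 and M phase genes (0.04) were higher, and these 11 lists had adjusted p from 0.371 to 0.866 with an estimated correlation. GPER1, at 476 ± 79.2 against 324 ± 7.25 normalized counts, had a log2 difference of 0.54 (SE 0.16). The chromatin remodeler SRCAP was at 4981 ± 262 against 2178 ± 320 (1.20, SE 0.26). TRIM14, an adaptor of antiviral signalling, was at 8393 ± 1780 against 2204 ± 1871.5 (2.22, SE 0.61), and SPCS2, a signal peptidase subunit, at -0.38. Counts of NPIPB8 (-3.21), a member of a family of near-identical copies, were uncertain. None of these genes passed limma over all 13827 genes (0 genes, smallest adjusted p = 1.00). At an unadjusted p under 0.05 there were 204, where chance gives 691, and edgeR called 0 genes and DESeq2 3. That number was 97 and 314 without 1 mg/kg replicates 1 and 3 and 393 without 10 mg/kg replicate 1. The groups did not overlap for 195 genes (1.41%, where chance gives 2.86%). Leaving out 1 mg/kg replicate 1 left 7 called lists and leaving out 1 mg/kg replicate 3 left 8 called lists and 1 called gene. Of the 15 lists those of hypoxia, immediate early and heat shock genes (3 lists) passed without any single library. NF-kB genes did not pass without 1 mg/kg replicate 1 or 3 (adjusted p = 0.0706 and 0.0546), nor interferon-stimulated genes without 1 mg/kg replicate 1 (0.0948). Direction turned for aminoacyl-tRNA synthetases without 10 mg/kg replicate 1 (0.936), for mitotic genes without it (0.458) or without 1 mg/kg replicate 4 (0.662), and for OXPHOS subunits without 1 mg/kg replicate 2 (0.878).

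In male mice at 1 mg/kg, interferon-stimulated genes were higher than with vehicle in 42 of 42 members, with a median log2 difference of 0.53. LGALS3BP, a secreted galectin ligand, stood at 97406 ± 10506 against 63512 ± 12783 normalized counts (0.63, SE 0.13). The ubiquitin-like conjugating enzyme gene UBE2L6 was at 7053 ± 525 against 4659 ± 1169 (0.63, SE 0.14) and the antiviral tether BST2 at 24606 ± 3257 against 13894 ± 6863 (0.93, SE 0.25). Of this list 12 members passed when adjusted over the list alone, with adjusted p = 0.0143 for LGALS3BP, 0.0145 for UBE2L6, 0.0296 for BST2 and 0.0363 for IFITM1 (0.97, SE 0.28). NF-kB and cytokine genes were lower in 24 of 24 members (median -0.52), and 6 passed when adjusted over the list alone. Among them the neutrophil chemokine CXCL8 was at 126 ± 23.6 against 605 ± 459 (-1.89, SE 0.50) and the cytokine CSF2 at 8.81 ± 8.12 against 68.1 ± 49.4 (-3.13, SE 0.85). BIRC3 was at 1643 ± 466 against 6367 ± 3773 (-1.70, SE 0.47), and these 3 genes had an adjusted p = 0.023. NFKBIZ was at -1.09 (SE 0.33, adjusted p = 0.0341). Cholesterol synthesis genes were higher in 25 of 25 members (median 0.23). By camera the adjusted p was 2.40e-22 for the interferon list, 1.49e-14 for the NF-kB list and 1.20e-08 for cholesterol synthesis. Each had adjusted p = 0.492 with an estimated correlation. With the mean of the list taken per library, the exact permutation p was 0.114 for the interferon list and 0.0571 for the NF-kB list (adjusted p = 0.543 for both). A single list could not pass this adjustment even at the smallest p that so few libraries allow. Lower lists were ribosome biogenesis and MYC-induced genes (median -0.18), p53 target genes (-0.25), G2 and M phase genes (-0.13), aminoacyl-tRNA synthetases (-0.13), heat shock genes (-0.15), serine, one-carbon and nucleotide synthesis genes (-0.09) and S phase genes (-0.08). Ribosomal proteins (0.08) and canonical histones (0.28) were higher. That made 12 of 38 lists, these 9 with adjusted p from 0.632 to 0.773 with an estimated correlation. Muscle and skin markers had 3 members that passed when adjusted over the list alone, in lists that did not pass. They were the oxygen carrier MB, at 143 ± 16.1 against 56.7 ± 35.4, ACTN2 (0.94) and the keratin KRT15 (-0.62). Other genes with small p were the tetraspanin CD9 (0.46, SE 0.10), the protease LGMN (0.49, SE 0.11), PANK4 (-1.90) and CDK6, a kinase of the G1 phase, at 1030 ± 271 against 1988 ± 459 (-0.96, SE 0.23). Over all 13900 genes limma called 0 genes (smallest adjusted p = 0.815), edgeR 0 and DESeq2 9. At an unadjusted p under 0.05 there were 819, where chance gives 695, with 435 and 1365 without vehicle replicates 1 and 4 and 543 without 1 mg/kg replicate 4. The groups did not overlap for 563 genes (4.05%, where chance gives 2.86%). Leaving out vehicle replicate 4 gave 16 called genes and leaving out vehicle replicate 1 gave 1. Of the 12 lists 5 passed without any single library, namely interferon-stimulated, NF-kB, cholesterol synthesis and ribosome biogenesis genes and aminoacyl-tRNA synthetases. Ribosomal proteins turned direction without 1 mg/kg replicate 4 (adjusted p = 0.682).

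**Figure D3:**
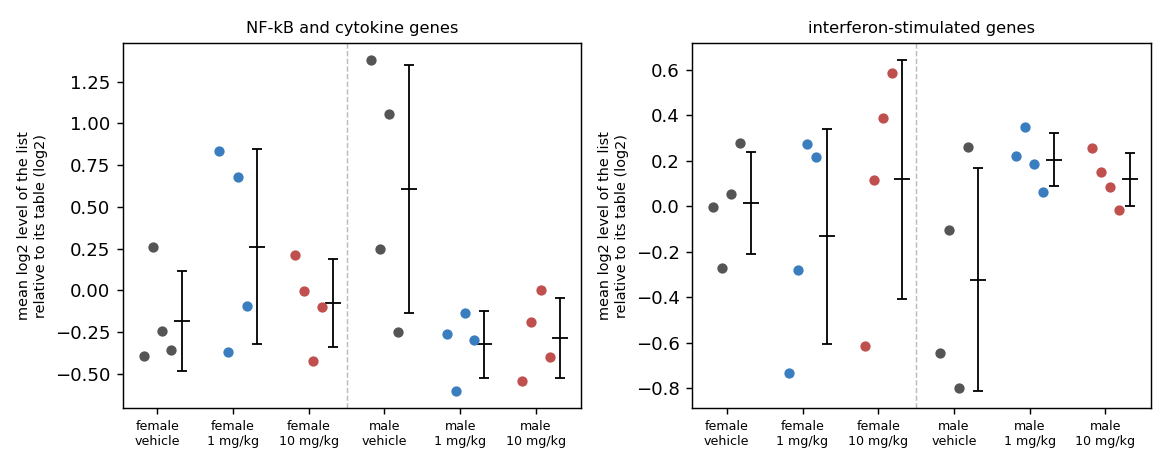
Mean log2 level of the NF-kB and cytokine list and of the interferon-stimulated list in each of the 24 libraries, relative to the mean of the library's own table, by host sex and dose; points are libraries and the black mark is the group mean with its SD. In male mice 3 of 4 vehicle libraries (0.24, 1.06 and 1.38) lay above all 8 asparagine libraries on the NF-kB list and the other vehicle library was at -0.25; vehicle libraries ranged from -0.80 to 0.26 on the interferon list.

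In male mice at 10 mg/kg the NF-kB and interferon lists were also called against vehicle. Both doses were set against the same vehicle libraries, so these calls are not an independent repeat. NF-kB and cytokine genes were lower in 23 of 24 members (median log2 difference -0.72), and 6 passed when adjusted over the list alone. NFKBIZ, an NF-kB cofactor, stood at 327 ± 111 against 896 ± 472 normalized counts (-1.36, SE 0.33). TNFAIP3, which ends NF-kB signalling, was at 919 ± 243 against 1862 ± 853 (-0.94, SE 0.30), BIRC3 at -1.77 and CXCL8 at -1.79. Interferon-stimulated genes were higher in 39 of 42 members (median 0.46), 5 of which passed when adjusted over the list alone. BST2 was at 27801 ± 5082 (1.10, SE 0.25), the ubiquitin-like modifier ISG15 at 0.85, IFI35 at 0.67 and LGALS3BP at 0.49. Mitochondrially encoded transcripts were lower in 13 of 13 members (median -1.08), 12 of which passed when adjusted over the list alone. MT-CO3, a subunit of cytochrome oxidase, was at 352980 ± 200550 against 739030 ± 376920 (-1.13, SE 0.39). These transcripts took 3.16% ± 1.83 of the normalized total at 10 mg/kg and 6.38% ± 3.17 with vehicle (exact permutation p = 0.114), with 1.55% and 1.74% in replicates 3 and 4. Mitotic genes were lower in 39 of 44 members (median -0.24), among them the cytokinesis factor ECT2 (-0.51, SE 0.19) and the spindle motor KIF11 (-0.35). By camera the adjusted p was 3.01e-09 for NF-kB, 2.76e-10 for interferon, 7.23e-09 for mitochondrial transcripts and 2.97e-08 for mitotic genes. For each adjusted p = 0.872 with an estimated correlation. Ribosomal proteins (median 0.14) and endothelial markers (0.42, 6 of 7 members, with PLVAP at 1.05) were higher. The p53 targets (-0.27), serine, one-carbon and nucleotide synthesis genes (-0.17) and S phase genes (-0.15) were lower, which made 9 of 38 lists, all with adjusted p = 0.872 with an estimated correlation. Members that passed when adjusted over the list alone, in lists that did not pass, were the collagens COL3A1 (1.52) and COL6A1 (0.50) among fibroblast markers, S100A4 (0.57), MB (1.52) and the carbonic anhydrase CA9, at 4054 ± 815 against 2197 ± 640 (0.91, SE 0.23). Other genes with small p were FAM83E, at 878 ± 256 against 332 ± 159 (1.45, SE 0.29), S100A2 (0.61, SE 0.13), the ubiquitin conjugating enzyme UBE2K (-0.60) and CDK6 (-0.95). Over all 13900 genes limma called 0 genes (smallest adjusted p = 0.461), edgeR 0 and DESeq2 15. At an unadjusted p under 0.05 there were 1474, where chance gives 695. The number moved in both directions with single libraries. It was 723, 777, 1466 and 2089 without vehicle replicates 1, 2, 3 and 4. It was 4025, 1574, 701 and 566 without 10 mg/kg replicates 1, 2, 3 and 4, and 555 without both replicates 3 and 4. A fit with fewer libraries also has less power. The groups did not overlap for 389 genes (2.80%, where chance gives 2.86%). Without vehicle replicate 4 there were 12 called genes, without vehicle replicate 1 or 10 mg/kg replicate 1 there was 1, and without vehicle replicate 3 there were 14 called lists. Of the 9 lists 5 passed without any single library: interferon-stimulated, NF-kB, mitotic and ribosomal protein genes and mitochondrial transcripts. Without replicates 3 and 4 of the 10 mg/kg group there was 1 called gene and the endothelial markers did not pass (adjusted p = 0.503, with 0.00896 to 0.872 over all alternatives). The median of the mitochondrial transcripts was then -0.36. The p53 list turned direction without vehicle replicate 1 (adjusted p = 0.919).

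The contrast between the doses in male mice likewise reuses libraries already compared with vehicle. Mitochondrially encoded transcripts were lower at 10 mg/kg than at 1 mg/kg in 13 of 13 members (median log2 difference -1.04). Of these 12 passed when adjusted over the list alone. Genes of cholesterol synthesis were lower in 21 of 25 members (median -0.28), including the last enzyme of the pathway, DHCR7 (-0.40). Those of fatty acid synthesis were lower in 14 of 19 (median -0.20), including the desaturases FADS1 (-0.48) and SCD (-0.49). By camera the adjusted p was 5.81e-12, 4.73e-07 and 0.00403 in that order, against adjusted p = 0.525 with an estimated correlation for each. The list mean per library separated the doses for cholesterol synthesis with an exact permutation p = 0.0286, the smallest that 4 against 4 libraries allow (adjusted p = 0.969). A single list with that p cannot pass the adjustment. Without replicates 3 and 4 of the 10 mg/kg group the median of the mitochondrial transcripts was -0.32. Mitotic genes (median -0.11), ribosome biogenesis and MYC-induced genes (0.08) and ribosomal proteins (0.08) completed 6 of 38 lists, with adjusted p = 0.966 with an estimated correlation. GPT, the alanine aminotransferase, was at 128 ± 31.6 against 67.4 ± 10.0 normalized counts (0.89, SE 0.23) and passed when adjusted over the list of asparagine, aspartate and glutamine metabolism alone. Other genes with small p were GNB1L (0.78, SE 0.18), CDK11A (0.78), which has a near-identical paralog, PANK4 (2.08) and SH3BGRL2 (-0.44). Over all 13900 genes limma called 0 genes (smallest adjusted p = 0.857), edgeR 0 and DESeq2 5, while limma with array weights called 3506. At an unadjusted p under 0.05 there were 477, where chance gives 695. The number was 297, 255 and 728 without 1 mg/kg replicates 1, 2 and 4, 2723, 211 and 151 without 10 mg/kg replicates 1, 3 and 4, and 266 without both of the latter 2. The groups did not overlap for 235 genes (1.69%, where chance gives 2.86%). Without replicates 3 and 4 of the 10 mg/kg group, whose mitochondrial shares were lowest, 2 genes were called and the mitotic and the ribosome biogenesis lists turned direction (adjusted p = 0.647 for both, at most 0.981 over all alternatives). Fatty acid synthesis (adjusted p = 0.0567, range 0.00148 to 0.663) and ribosomal proteins (0.979, range 2.49e-08 to 0.981) then did not pass. Mitochondrial transcripts and cholesterol synthesis genes were the 2 of 6 lists that passed without any single library, and fatty acid synthesis did not without 10 mg/kg replicate 2 (adjusted p = 0.0511). Ribosomal proteins turned direction without 1 mg/kg replicate 2 (0.809). Without 10 mg/kg replicate 1 there was 1 called gene.

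The sex difference in the effect of 1 mg/kg was tested as the female effect minus the male effect. NF-kB and cytokine genes had the more positive effect in females for 22 of 23 members (median difference 0.81 on the log2 scale), and 11 passed when adjusted over the list alone. BIRC3 had an effect of 1.35 in females and -1.70 in males (difference 3.05, SE 0.64, adjusted p = 0.615 over all genes). The differences were 1.78 (SE 0.49) for NFKBIZ, 3.76 for CSF2 and 1.10 for NFKBIA. Interferon-stimulated genes had the more negative effect in females for 42 of 42 members (median -0.64), with LGALS3BP at -0.27 in females and 0.63 in males (difference -0.90, SE 0.21), the only 1 to pass when adjusted over the list alone. By camera both lists had an adjusted p of 4.38e-16, against adjusted p = 0.392 for NF-kB and 0.595 for interferon with an estimated correlation. Also called were ribosome biogenesis and MYC-induced genes (median 0.27), p53 targets (0.36), mitotic genes (0.19), aminoacyl-tRNA synthetases (0.23), serine, one-carbon and nucleotide synthesis genes (0.17) and S phase genes (0.16). Negative differences were called for ribosomal proteins (-0.18), cholesterol synthesis genes (-0.19) and histones (-0.62). That made 11 of 37 lists, these 9 with adjusted p = 0.7503 with an estimated correlation. Of the estrogen receptor and estrogen-induced genes GPER1 (-0.71, SE 0.23), MYC (0.53) and CELSR2 (-0.53) passed when adjusted over the list alone, and the list did not (camera adjusted p = 0.651). IRAK2, a kinase of interleukin-1 signalling, had an effect of 0.57 in females and -0.97 in males (difference 1.54, SE 0.40), and the cell surface protein LY6D a difference of -2.22. Over 13735 genes limma and edgeR called 0 genes and DESeq2 14, with 677 at an unadjusted limma p under 0.05 where chance gives 687. That number was 402 without male vehicle replicate 1 and 423 without male 1 mg/kg replicate 4. Without male vehicle replicate 4 there were 3 called genes and without male vehicle replicate 2 there was 1. The NF-kB, interferon and ribosome biogenesis lists were the 3 of 11 that passed without any single library.

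The same contrast was tested for 10 mg/kg. It used the same vehicle libraries of both sexes, so lists and genes that stand out at both doses are not an independent repeat. Mitotic genes had the more positive effect in females for 40 of 44 members (median difference 0.35), with ECT2 at 0.78 and KIF11 at 0.67, and ribosomal proteins the more negative effect for 55 of 57 (median -0.37). Mitochondrially encoded transcripts differed by a median of 1.26 (13 of 13 members) and NF-kB genes by 0.51 (20 of 23). BIRC3, at 0.97 in females and -1.77 in males (difference 2.74, SE 0.64), and NFKBIZ, with a difference of 1.83, were the 2 members of the NF-kB list that passed when adjusted over the list alone. By camera the adjusted p was 2.87e-07, 1.25e-11, 7.89e-06 and 2.29e-05 in that order, and for each adjusted p = 0.733 with an estimated correlation. S phase genes (median 0.22), aminoacyl-tRNA synthetases (0.24), serine, one-carbon and nucleotide synthesis genes (0.25) and p53 targets (0.31) also had positive differences. Unfolded protein response genes (-0.28), interferon-stimulated genes (-0.22), histones (-0.51) and immediate early genes (-0.33) brought the count to 12 of 37 lists, with adjusted p of 0.733 or 0.752 with an estimated correlation. In lists that did not pass, members that did when adjusted over the list alone included NRIP1 (1.37, SE 0.33), RARA (-0.81), SIAH2 (-0.44) and the protease CTSD (-0.62) among estrogen-induced genes. Others were the transporters SLC7A6 (1.76) and SLC1A3, at -1.30 in females and 0.20 in males, and GPT (-1.53, SE 0.39). IGF2BP3, an RNA-binding protein gene named after its values were seen because its symbol lies outside the naming rule, had the smallest p (difference 1.46, SE 0.24, adjusted p = 0.0581). It was followed by PALM3, at -0.89 in females and 0.61 in males (SE of the difference 0.29, adjusted p = 0.178), and ELK3, at 0.52 and -0.51 (difference 1.03, SE 0.20, adjusted p = 0.178). Over 13735 genes limma and edgeR called 0 genes, DESeq2 46 and limma with array weights 666. At an unadjusted limma p under 0.05 there were 1890, where chance gives 687. The number was 1164 without female vehicle replicate 3, 3469 and 1005 without male 10 mg/kg replicates 1 and 4, and 773 without male 10 mg/kg replicates 3 and 4. Without male vehicle replicate 4 there were 3 called genes and without female vehicle replicate 4 or male 10 mg/kg replicate 1 there was 1. Without male 10 mg/kg replicates 3 and 4 the median difference of the mitochondrial transcripts was 0.46 and the immediate early genes did not pass (adjusted p = 0.250, range 0.00591 to 0.733). Of the 12 lists 6 passed without any single library: mitotic, S phase, NF-kB and ribosomal protein genes, aminoacyl-tRNA synthetases and mitochondrial transcripts.

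Effects of the 2 doses were then compared across genes, which are not independent replicates. In females the log2 differences of 1 and 10 mg/kg from vehicle correlated with r = 0.58 over 13827 genes, where shared vehicle libraries alone gave 0.50 in 100 simulated draws (covariance 0.0724 against 0.0575). In these genes 74.5% had the same sign against 66.7% simulated. Each gene was simulated on its own, so variation shared between genes was absent. An excess over the simulated values therefore cannot be told apart from such variation. With the vehicle libraries divided 2 and 2 between the doses, r was 0.05 (range -0.08 to 0.11). In males r was 0.63 against 0.50 simulated (covariance 0.0915 against 0.0471), with 72.3% of the same sign against 66.6%, and 0.17 (range 0.08 to 0.21) with divided vehicle libraries. Female and male effects, which share no libraries, correlated with r = -0.10 at 1 mg/kg and -0.21 at 10 mg/kg, with the same sign in 40.5% and 38.0% of genes. No simulated value was set beside these correlations. Both use the same vehicle libraries, so they are not independent of each other. They therefore cannot decide whether asparagine acts in opposite directions in the sexes. With the mean of each called list taken per library, the exact permutation p in females ran from 0.171 to 0.657 at 1 mg/kg, from 0.114 to 0.571 at 10 mg/kg and from 0.0571 to 0.857 between doses, with smallest adjusted p of 0.943, 0.961 and 0.913. In males it ran from 0.0571 to 0.571, from 0.0857 to 0.4 and from 0.0286 to 0.571, with smallest adjusted p of 0.543, 0.706 and 0.969. This test cannot give a p below 0.0286, so a single list could not pass after adjustment and these adjusted p cannot decide. When the libraries of a comparison were divided into groups of 4 in every way, 13 to 26 of 35 divisions, the real one included, gave at least as many called lists as the real one for the comparisons within a sex. For the sex differences at 1 and 10 mg/kg not every division was made. There it was 58 and 39 of 100, the real one and others drawn at random.

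Several lists close to the study's question passed in none of the 8 contrasts. Asparagine, aspartate and glutamine metabolism (26 members measured) had medians between -0.06 and 0.10 (smallest camera adjusted p = 0.0752). ATF4 targets of the amino acid response lay between -0.04 and 0.08 (0.545), amino acid transporters between -0.10 and 0.07 (0.136) and mTORC1 signalling genes between -0.05 and 0.02 (0.445). Estrogen synthesis and turnover genes lay between -0.18 and 0.18 (smallest adjusted p = 0.0530). Nor did a call come from NRF2 targets (0.445), WNT targets and stem cell genes (0.428), antigen presentation (0.218), autophagy and lysosome genes (0.0517), enterocyte and goblet genes (0.108) or epithelial-mesenchymal transition genes (0.0738), the numbers being the smallest camera adjusted p. Among markers of cells other than tumor cells, fibroblasts (0.0527), leukocytes (0.156), muscle (0.261), keratinocytes (0.183) and, in the male table, adipocytes (0.464) gave no call. No erythroid marker reached a mean of 10 (HBA2 averaged 4.68 and 4.38 normalized counts). Within its cell type the most abundant marker was COL6A1 for fibroblasts (25516 and 28458 in the female and male tables). It was DSC3 for keratinocytes (3452 and 4307), EGFL7 for endothelial cells (2662 and 3845), PPARG for adipocytes (891 and 963) and CORO1A for leukocytes (476 and 767). Over 57 tests of library measures between groups (totals, genes detected, shares of the most abundant genes and marker means) the smallest exact permutation p was 0.0571 and the smallest adjusted p 0.905. A single measure could not pass this adjustment with so few libraries per group.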

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

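The test of PARN's spread in the male table, the test of the NF-kB list without single vehicle libraries, the rescaling to a total without mitochondrial transcripts and the values without male 10 mg/kg replicates 3 and 4 were chosen only after the results were seen.

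Single libraries stood far from the other 3 of their group in 17 of 320 groups tested (5.31%), where chance alone gives about 5%. The measure is the gap of the extreme library to its nearest neighbour as a share of the group's range, set against Dixon's 95% critical value. The endothelial marker score of female vehicle replicate 4 (-0.24, others 0.10 to 0.16) had a share of 0.850. Female 10 mg/kg replicate 3 stood apart for PARN (24.8 normalized counts, others 13.6 to 15.0, share 0.877), for WDR37 (1433.5, share 0.864) and for NPIPB8 (11.3 against 0 in the others, share 1). Female vehicle replicate 3 stood apart for PALM3 (1161, others 983 to 991, share 0.956) and TMEM35B (680, share 0.880), and female vehicle replicate 1 for TLR1 (78.7, share 0.833). Among female 1 mg/kg libraries, replicate 1 was high for TRIM14 (4985, others 1000.2 to 1613, share 0.846), replicate 2 for ASNS (4008, others 2650.4 to 2878, share 0.832) and replicate 3 for GREB1L (165, share 0.832) and NPIPB8 (47.1, share 0.857). Male 10 mg/kg replicate 4 was low for SH3BGRL2 (448, others 573 to 588, share 0.890). ESR1 had reads in only 1 library of female 1 mg/kg, male vehicle and male 10 mg/kg mice, each with a share of 1. The glycolysis score of female vehicle replicate 2 (0.15, share 0.852) and the OXPHOS score of male vehicle replicate 1 (0.23, share 0.892) were high in their groups. Female 10 mg/kg replicate 1 was in none of the 17 flags but differed from its group in depth. It had 26048864 reads (others 61243711 to 75253823) and 14132 genes detected (others 14958 to 15200). On the first principal component of the female table (23.2%) it lay at -81.5, with all other female libraries between -25.6 and 28.6. The cause was not tested.

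Camera at its preset correlation called a difference between female and male effects for 11 lists at 1 mg/kg and 12 at 10 mg/kg. Of 100 splits of the libraries, the real one and others drawn at random, 58 and 39 gave at least as many. Both contrasts use the same vehicle libraries, so a list called at both doses is not an independent repeat. At 1 mg/kg the median female minus male log2 difference was 0.81 for NF-kB and cytokine genes, 0.36 for p53 targets, 0.27 for ribosome biogenesis and MYC-induced genes and 0.23 for aminoacyl-tRNA synthetases. It was 0.19 for mitotic genes, 0.17 for serine, one-carbon and nucleotide synthesis genes and 0.16 for S phase genes. Negative differences were -0.64 for interferon-stimulated genes, -0.62 for histones, -0.19 for cholesterol synthesis genes and -0.18 for ribosomal proteins. At 10 mg/kg it was 1.26 for mitochondrially encoded transcripts (0.46 without male 10 mg/kg replicates 3 and 4), 0.51 for NF-kB and cytokine genes, 0.35 for mitotic genes and 0.31 for p53 targets. Serine, one-carbon and nucleotide synthesis genes stood at 0.25, aminoacyl-tRNA synthetases at 0.24 and S phase genes at 0.22. Negative differences were -0.51 for histones, -0.37 for ribosomal proteins, -0.33 for immediate early genes, -0.28 for unfolded protein response genes and -0.22 for interferon-stimulated genes. None of them passed with an estimated correlation (smallest adjusted p = 0.392 at 1 mg/kg and 0.733 at 10 mg/kg).

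Chance could not be excluded for any count of called lists, nor for the single genes called in females, when the same libraries were regrouped with the real split included. For genes in females, 5 of 35 splits gave at least the real 1 at 1 mg/kg (highest other 3018) and 3 of 35 gave at least the real 1 at 10 mg/kg (highest other 1). Where the real count was 0, every split gives at least as many (35 of 35 within a sex, 100 of 100 for the sex differences), so those counts say nothing about chance. The highest other there was 1 between the female doses. In males the highest other was 2 at 1 mg/kg, 356 at 10 mg/kg and 2811 between doses. For the sex differences it was 3 at 1 mg/kg and 2319 at 10 mg/kg. The count of lists in females was 9 at 1 mg/kg (26 of 35 splits as large, highest other 21), 11 at 10 mg/kg (19 of 35, highest 20) and 15 between doses (13 of 35, highest 21). In males it was 12 (24 of 35, highest 20), 9 (22 of 35, highest 17) and 6 (22 of 35, highest 15). The sex differences had 11 lists (58 of 100, highest 21) and 12 (39 of 100, highest 20). The largest splits were picked after their counts were seen. The split with 3018 genes set female vehicle replicates 1 and 4 with 1 mg/kg replicates 3 and 4 against the rest. It may point to a structure of the samples apart from the groups, which was not tested. The splits with 356 and 2811 genes set 10 mg/kg replicate 1 with replicates 1, 2 and 3 of male vehicle and of male 1 mg/kg. In them 10 mg/kg replicate 1 only changed places with replicate 4 of the other group, so they lie close to the real groups.

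The lower AC004922.1 at 1 mg/kg and PARN at 10 mg/kg were the called genes of the female comparisons. For PARN 0 annotated genes had exons that overlap its own on the same strand, which argues against reads shared with genes on that strand. Overlaps on the opposite strand were not examined. Since the strand setting of the counting is not given, reads shared with such genes stay open. Shared reads also stay open for AC004922.1. Genes that overlap another coding gene on the same strand were over-represented among the most variable 5% of the male table (odds ratio 2.49, 95% interval 2.06 to 2.98, Fisher's exact test). In that table AC004922.1 lay at percentile 100. PARN's spread within male groups lay at percentile 98.6 among genes of like mean, so its fall may come from a level that varies between libraries whatever the group. An effect of asparagine also stays open for both genes and was not tested apart from the comparison itself.

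The NF-kB and cytokine list was lower in male mice given asparagine, with a difference in mean log2 score of -0.89 at 10 mg/kg. Unequal sequencing depth is argued against, since 99.1% of that difference was left after all male libraries were thinned to the same number of reads. A single vehicle library could account for part of it and cannot be told apart from a group effect with 4 libraries. The share left was 71.1% without vehicle replicate 1, 83.2% without replicate 3, 114% without replicate 2 and 132% without replicate 4. Asparagine itself stays among the open explanations, untested beyond the comparison.

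Mitochondrially encoded transcripts were lower in male mice at 10 mg/kg (median log2 difference -1.08). After rescaling to the total without these transcripts 103% of the shift was left (median -1.11). That scaling moves all genes of a library alike and changed the median little. It therefore cannot decide whether the authors' normalization had a part in the shift. Without replicates 3 and 4 of the 10 mg/kg group the median was -0.36, so most of its size rested on those libraries. RNA quality or tissue handling of those tumors was not recorded in the labels and was not tested, and an effect of asparagine stays open as well.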

How the results depend on the processing

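The values without male 10 mg/kg replicates 3 and 4 and those scaled to a total without mitochondrial transcripts were chosen after seeing the data, and all other alternatives were planned. Comparisons are given in the order of the report: female 1 mg/kg, 10 mg/kg and 10 against 1 mg/kg, the same for males, and the sex differences at 1 and 10 mg/kg. AC004922.1 kept its direction and its call under all 21 alternatives (log2 -3.59 to -3.17, adjusted p 2.85e-21 to 0.0305). The 4 other scalings moved the medians of the 85 called lists by at most 0.04 log2 and turned the direction of 0, a shift too small to test their stability. With an estimated correlation and with fry 0 lists were called in each of the 8 contrasts. DESeq2 called 6, 8, 3, 9, 15, 5, 14 and 46 genes, and on simulated data it called more unchanged genes than limma. Array weights, from 0.226 for male 10 mg/kg replicate 1 to 5.08 for male 1 mg/kg replicate 1 among males, gave 2 genes at 10 mg/kg in females, 1 between female doses, 2 at 1 mg/kg in males, 3506 between male doses and 666 for the sex difference at 10 mg/kg. A fit of only the compared groups gave 1 gene between female doses and 1 at 1 mg/kg in males. Without the filter 2 and 1 genes were called at 1 and 10 mg/kg in males. Without male 10 mg/kg replicates 3 and 4 there was 1 gene against vehicle and 2 against 1 mg/kg. In the latter the mitotic and ribosome biogenesis lists reversed (adjusted p = 0.647 for both, and otherwise 0.000407 to 0.252 and 7.46e-05 to 0.339 without single libraries). For these changed results the cause was not tested.

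Leaving out single libraries gave 1 to 2 called genes at 1 mg/kg in females (2 without 1 mg/kg replicate 3) and 0 to 1 at 10 mg/kg (0 without vehicle or 10 mg/kg replicate 1, 2 or 4). It gave 0 to 1 between female doses (1 without 1 mg/kg replicate 3). In males it gave 0 to 16 at 1 mg/kg (16 without vehicle replicate 4, 1 without replicate 1), 0 to 12 at 10 mg/kg (12 without vehicle replicate 4, 1 without vehicle or 10 mg/kg replicate 1) and 0 to 1 between doses (1 without 10 mg/kg replicate 1). The sex differences had 0 to 3 (1 mg/kg: 3 without male vehicle replicate 4, 1 without replicate 2; 10 mg/kg: 3 without male vehicle replicate 4, 1 without female vehicle replicate 4 or male 10 mg/kg replicate 1). Called lists ranged from 4 to 16, 8 to 13, 7 to 17, 10 to 15, 7 to 14, 4 to 9, 8 to 13 and 9 to 14. The extremes beyond 1.5 times came without female 1 mg/kg replicate 1 (4 lists) or 4 (16 lists) at 1 mg/kg, without 1 mg/kg replicate 1 (7 lists) or 3 (8 lists) between female doses, and without vehicle replicate 3 (14 lists) at 10 mg/kg in males. The adjusted p of PARN ran from 0.0281 to 0.140 and its log2 difference from -3.43 to -3.08. The cause was not tested.

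Lists that reversed without 1 library are given with the range of adjusted p over single libraries. At 1 mg/kg in females they were S phase genes (8.13e-06 to 0.480, reversed at 0.303 without 1 mg/kg replicate 2), interferon-stimulated genes (8.89e-07 to 0.639, 1 mg/kg replicate 1), ribosomal proteins (7.92e-11 to 0.884, at 0.8286 without vehicle replicate 2) and histones (2.92e-05 to 0.854, vehicle replicate 2). At 10 mg/kg in females the OXPHOS subunits did so (4.82e-05 to 0.916, at 0.856 without vehicle replicate 2). Between female doses they were aminoacyl-tRNA synthetases (7.77e-08 to 0.936, 10 mg/kg replicate 1), mitotic genes (1.63e-10 to 0.827, at 0.662 without 1 mg/kg replicate 4 and 0.458 without 10 mg/kg replicate 1) and OXPHOS subunits (3.08e-07 to 0.977, at 0.878 without 1 mg/kg replicate 2). In males they were ribosomal proteins at 1 mg/kg (6.37e-09 to 0.682, 1 mg/kg replicate 4), p53 targets at 10 mg/kg (3.15e-05 to 0.919, vehicle replicate 1) and ribosomal proteins between doses (2.49e-08 to 0.825, at 0.809 without 1 mg/kg replicate 2). The cause was not tested.

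Low counts limited the core genes: CYP19A1 had 0 to 11 reads, ESR1 at most 6 and ESR2 2 to 33. The log2 difference of CYP19A1 ran from -0.92 to 0.54 at 10 mg/kg in females (reversed without vehicle replicate 1 or 4 or 10 mg/kg replicate 1) and from -0.25 to 0.99 at 1 mg/kg in males (vehicle replicate 1 or 4, 1 mg/kg replicate 1). ESR1 at 10 mg/kg in males ran from -0.72 to 0.51 (vehicle replicate 1). ESR2 at 10 mg/kg ran from -0.46 to 0.082 in females (vehicle replicate 3, 10 mg/kg replicate 4) and from -0.50 to 0.60 in males (vehicle replicate 3 or 4, 10 mg/kg replicate 1 or 2), and was 0.025 in males with a pseudocount of 5. ASNS at 1 mg/kg ran from -0.028 to 0.18 in females (1 mg/kg replicate 2) and from -0.11 to 0.043 in males (vehicle replicate 1 or 4). The correlation of the effects of both doses, 0.58 in females and 0.63 in males, was 0.051 and 0.17 with divided vehicle libraries, since the shared libraries are then removed.

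The replicate numbers were not taken to pair the samples, since the labels tie them to no shared animal, litter or day and not every pair of the same number correlated above 0.1. Libraries of the same number in different groups had a mean correlation of deviations of 0.04 in females (3 of 12 pairs above 0.1) and 0.09 in males (5 of 12). For libraries of different numbers it was -0.01 in females and -0.03 in males. Of 12 libraries 3 in females and 8 in males correlated best with their own number. The male values are a hint of pairing from the data, not from the design. With the replicate number as a block 1, 0, 0, 0, 2, 0, 0 and 1 genes were called (PARN at adjusted p = 0.0668, with 7.61e-10 to 0.140 over all alternatives), and 13, 13, 14, 13, 10, 6, 12 and 12 lists. Genes at an unadjusted p under 0.05 at 10 mg/kg in males were 2474 with the block and 1474 without. At 1 mg/kg in males the smallest limma adjusted p was 0.061 with the block and 0.815 without.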

Other observations

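The correlation between the NF-kB and interferon scores was chosen for testing only after the list results were seen, while the marker lists of other cell types were fixed in advance.

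Genes listed as markers of cells other than tumor cells had levels that differed by type. Of 22 fibroblast and pericyte markers 15 reached a mean of 10 normalized counts in both tables and 6 a mean of 1000, with a median over members of 59.2 in females and 66.3 in males. Of 12 keratinocyte markers 8 reached a mean of 10 and 4 a mean of 1000 (medians 24.8 and 26.4). Endothelial markers reached a mean of 10 for 7 of 18 members (medians 6.12 and 7.55) and muscle markers for 7 of 16 (medians 6.49 and 7.92). Leukocyte markers did so for 8 of 22 members in females and 9 in males (medians 1.71 and 1.88), and adipocyte markers for 1 and 3 of 10 members. Erythroid markers did so for 0 of 8. The most abundant muscle marker was ACTN2 in females (61.3) and MB in males (116). Members below a mean of 10 included DCN (0.27 in females and 0.29 in males), PECAM1 (1.54 and 2.60) and PTPRC (0.82 and 0.86). The levels alone therefore do not show that such cells were present. Which of these reads came from tumor cells and which from mouse cells was not tested.

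A hypothesis drawn from the male comparisons was that NF-kB and interferon-stimulated scores move apart between libraries within groups, as shared variation between tumors. Deviations of the 12 libraries of a table from their group means were correlated, 2 relations in all. In males Pearson's r was -0.89 (permutation p = 0.0314, adjusted p = 0.0628, 100000 resamples) and Spearman's rho -0.82 (p = 0.0566, adjusted p = 0.113), with r = -0.78 without the 2 libraries farthest from the median NF-kB score. In females r was -0.44 (permutation p = 0.227) and rho -0.32 (p = 0.352), with r = -0.46 without the 2 farthest. Variation between tumors that is independent of asparagine may thus underlie part of the opposite shifts of these lists in males, but neither table passed after adjustment and the 12 libraries of each leave it undecided.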
